A study of Homo sapiens with 6 samples.

How the data were processed

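RNA-seq was described for 6 samples of the MMNK1 line, 3 with a scrambled hairpin and 3 with a hairpin against ARID1A. Groups and set numbers were taken from the sample titles. Per the labels' protocols, hairpins were delivered by lentivirus, infected cells were selected with an antibiotic, and libraries were made with a stranded mRNA kit. The submitters' processing notes name bcl2fastq 2.19.1, STAR 2.7.0f, featureCounts, Subread 1.6.4, DESeq2 1.22.1 and genome build hg38, without giving the role or settings of each. The annotation release used for counting is not given in the sources used here. The authors deposited normalized counts, as the name of the table states, and each of its rows is a transcript.

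The table holds 6 value columns, and all 6 were left out because 0 of them could be tied to a sample by its heading. The tests planned before the data were examined, a limma fit at the gene level and tests of the 38 gene lists, were not run under any setting. Those plans also assumed gene-level values, whereas the table is per transcript.

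Only the header line and the identifier columns were used. The value columns were looked at when the table was first inspected, but none of their values entered the results. With Python 3.11.15 and pandas 2.3.3, transcript identifiers were matched to the GENCODE 29 primary assembly annotation, first with and then without the version suffix. Gene names of the lists were looked up exactly as written, without trying other symbols of the same gene. The coordinates of ARID1A are those of GENCODE 29 on GRCh38. Some rows may have been left out of the table as used here, so that a name not found in it is not evidence of its absence from the study. No depth, interval or error is given, because no measured value is reported.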

Results

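The study asked how lowering ARID1A, a DNA-binding subunit of the canonical BAF form of the SWI/SNF chromatin remodelling complex, alters gene expression in MMNK1 cells, an immortalized line of human cholangiocytes, the epithelial cells that line bile ducts. Poly(A)-selected, strand-specific RNA-seq libraries were described for 6 samples. Cells carrying a scrambled short hairpin made up 3 of them, and cells carrying a hairpin against ARID1A made up the other 3. The labels number the samples of each group as sets 1, 2 and 3.

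Expression was deposited as a single table of normalized counts with 6 value columns, headed only by the numbers 1 to 6. None of these headings is the title or description of a sample, and none names a hairpin. The 3 headings that recur in the labels do so as set numbers, each shared by 2 samples, 1 from each group. Assigning a column by its position would have been a guess, and assigning it by its ARID1A level would have presumed the knockdown that the comparison was meant to check. The comparison of ARID1A knockdown with the scrambled control was therefore not made, and no expression level, fold change or depth per library is reported. The extent of the ARID1A knockdown was likewise not analysed here.

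The table lists 226030 transcripts under 58716 gene names, and 34785 of those names have a single transcript. Each row carries an Ensembl transcript identifier with its version. Of these identifiers, 191177 (84.6%) occur with the same version in the human annotation used here, the GENCODE 29 primary assembly. Of those, 188125 carry the same gene name in both. The remaining identifiers have no such match, so the table was not built on exactly this annotation. ARID1A (ENSG00000117713.19) is a protein-coding gene on the plus strand of chromosome 1, from 26693236 to 26782110 in GRCh38, by GENCODE 29. The table lists 17 transcripts of ARID1A, and GENCODE 29 also holds 17. Only these counts were compared, and whether the transcripts are the same was not checked.

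The 38 gene lists fixed before the data were examined, which cover pathways, cell type markers and complexes, hold 873 distinct gene names. Of these, 867 occur in the table, and 33 lists have every member named there. Names are missing from the SWI/SNF subunits other than ARID1A (26 of 27 named), the hepatocyte markers (23 of 24) and the G2/M genes (29 of 30). They are also missing from the interferon-stimulated genes (30 of 32) and the ERK feedback genes (19 of 20). A missing name need not be a missing gene, since some lists hold synonyms. The ERK feedback list writes CXCL8 by its older symbol IL8. CXCL8 itself is among the secreted inflammatory factors, of which 26 of 26 are named. The interferon-stimulated list holds the same gene as both DDX58 and RIGI. The TGF-beta induced genes, targets of a growth factor pathway that restrains epithelial growth, have 38 of 38 members named. The cholangiocyte markers have 25 of 25 named, the epithelial markers 30 of 30 and the mesenchymal markers 25 of 25. A name in the table shows that the gene was in the annotation used for counting, not that it was expressed.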

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

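The share of transcript identifiers found in the GENCODE 29 primary assembly annotation was 84.6% with the version suffix. It was 90.8% without the suffix, an alternative chosen after seeing the data. None of the alternatives planned for the expression comparison was run, since the 6 value columns were tied to no sample. No paired analysis was possible because the columns carry no set number that could be matched to a sample.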
